A study of Homo sapiens with 4 samples.

How the data were processed

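Signals came from 2 two-colour Agilent arrays, each with 61657 spots for transcripts and 1319 control spots, of which 308 were negative controls. The samples were total RNA on both arrays (Cy3), cytoplasmic RNA on array 1 and nuclear RNA on array 2 (both Cy5). Dyes come from the titles and the label field. The labelling text shared by all samples describes Cy3 only. There was no dye swap, and nothing in the labels says whether the 2 total samples come from separate cultures, so the spread between them can be technical.

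Spot intensity values are the median pixel brightness of the spot and of its local background in each channel, per the file headers from Agilent Feature Extraction 10.7.3.1 on a design that names genome build hg19. The log10 ratio of the deposited files is the scanner software's Cy5 over Cy3 ratio of background-subtracted and dye-normalised signals. The other deposited values used were flags of 0 or 1 per spot (well above background, saturated, outlier), per the file headers. The authors' value table holds log2 values with the same median, 4.23, in all 4 columns. Each column followed the processed signal of its own channel at a Spearman correlation of 0.9999 across probes, so direction and source are known. A correlation of ranks does not show the scale, and the steps that gave the columns equal quantiles are not given in the sources used here.

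Background was corrected with limma 3.58.1 (R 4.3.3) by the normexp method with an offset of 50, on all spots, and each array was normalised by loess with control spots at weight 0. The design fixed in advance named the mean signal of each spot. The files used hold no such column, and the median signal was used. Spots with an outlier flag (167 on array 1, 133 on array 2) were left out, and 22 probes had no value on an array. Spots of one probe were averaged, then probes of one gene. Nuclear over cytoplasmic is the log2 Cy5 over Cy3 ratio of array 2 minus that of array 1, in which a probe's dye effect cancels. Levels per channel were taken after Aquantile normalisation between arrays. A probe entered when its total signal was well above background on both arrays, in at least 0.5 of its spots, a filter that looks at neither fraction. The remaining 19950 units are genes with a symbol or single unnamed probes. For a gene selected by the naming rule given below and dim in one fraction, which was KCNQ1OT1 alone, a bound was computed. The dim side was set to the higher of the gene's own level and the lowest level among probes well above background in that channel. The gene's own level was the higher (log2 6.275 against 6.017). The value is therefore the plain ratio of the Cy5 levels, with no allowance for noise.

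Names were taken from RefSeq accessions in the files, matched without versions to a table for assembly GRCh38.p14. Since the arrays were designed on another build, no coordinates are given. Of 8216 probes with an NM_ or NR_ accession, 8107 matched, for 7399 symbols, and 109 did not. Another 21781 catalogue probes carry no accession, 87 carry another kind of accession and 28523 are custom probes in sets of 15605 and 12918. Total signal was well above background for 58.5% of mRNA probes, 48.9% of catalogue probes without an accession, 19.0% of the larger and 14.1% of the smaller custom set. XIST, TSIX and Y-linked genes were left out of every result. No sequence of a probe was used here.

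Error was described in 3 ways. The SD of total sample 2 minus total sample 1 was 0.162 in the dimmest, 0.242 in the middle and 0.335 in the brightest 6650 units. The median SD of the nuclear over cytoplasmic ratio was 0.158 over the spots of the 38 probes with at least 10 spots. It was 0.357 over the probes of 311 genes with several. In 192 of these genes all probes lay on one side of 0. Probes past 2-fold in opposite directions were found in 2 genes, MCTS1 (-1.15 and 1.40) and NCK2 (-1.40 and 3.41).

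With 1 cytoplasmic and 1 nuclear sample the main calls rest on no test and no p-value is given. They use a fixed limit of 2-fold (log2 of 1). Lists of genes fixed before the data were examined (22 lists, 14 with at least 3 measured genes) are described by the percentile of their median among 10000 random lists of the same size, matched on mean total signal in 20 bins. Percentiles under 2.5 or over 97.5 are called outside the range of random lists. Custom probes were compared with mRNA probes in the same way. These percentiles describe these hybridisations, since genes are not replicates. The genes named were set by rule: 13 genes fixed in advance, most of known location, then the 10 mRNAs and up to 8 lncRNAs with the highest and lowest ratios among those well above background in every channel, with all probes on one side of 0 and total between the fractions, then the 2 highest and 2 lowest members of each list that were well above background in both fractions. A few further list members are named as examples, and not every gene the rule selects is named.

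The steps were tested on simulated data. In a simulated pair of arrays with 58620 probes, 200 were given known nuclear over cytoplasmic changes. Of those set to a log2 ratio of 2, 88% passed 2-fold, with a median of 1.39, and of those set to -2, 92% passed with a median of -1.61. In the brightest group the medians were 1.91 and -2, and in the dimmest 1.20 and -1.09, so the offset shrinks the ratios of dim probes. Of those set to 1 or -1, 26% and 16% passed. The simulated changes were few and equal in number in both directions, whereas 3019 and 2148 of 19950 units passed 2-fold on the real arrays. These rates therefore do not show how loess acts when many probes change. None of 20080 unchanged probes passed, but the simulated noise was set below the spread seen between the 2 total samples. That count therefore does not give the rate of false calls on the real arrays. In 200 simulated lists of 20 among 4400 genes, 6% of unshifted lists and 99% of lists shifted by a log2 of 1 fell outside that range.

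Alternatives were fixed before the data were examined: the scanner software's log ratio, median centring without loess, no background subtraction, the authors' value table, 3 other filters on dim probes, the brightest probe per gene, a single total sample as reference, thresholds of 1.5-fold and 4-fold, random lists without matching, and a limma fit of the 4 channels on 3 groups. That fit has 1 residual degree of freedom, from the 2 total samples, assumes that the lone fractions vary like them, and called units at an adjusted p under 0.05 and at least 2-fold. The limma fit has no term for the array, so a fraction is not paired with the total sample of its own array. Its nuclear over cytoplasmic ratio sets the Cy5 levels of the 2 arrays directly against each other. Leaving out probes with a mean total signal at or above a log2 of 14, and genes whose probes differ in sign, was added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.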

Results

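P493-6 is an established human B-cell line in which MYC is expressed from a transgene that tetracycline switches off. The cells were kept in tetracycline (0.1 µg/mL) for 72 h in all 4 samples, and without an untreated sample the extent of MYC repression was not measured. RNA from the cytoplasmic fraction, from the nuclear fraction and from whole cells (total RNA, 2 samples) was compared on 2 arrays that carry probes for mRNAs and for long noncoding RNAs (lncRNAs). Array 1 paired the cytoplasmic sample (Cy5) with total sample 1 (Cy3). Array 2 paired the nuclear sample (Cy5) with total sample 2 (Cy3). The study asked where in the cell each transcript lies. Of 61657 spots, 23938 were well above background for total sample 1, 18753 for the cytoplasmic sample, 22757 for total sample 2 and 22421 for the nuclear sample, and none was saturated. Each fraction is 1 sample, so no value below has a replicate of its fraction and the calls in the comparisons rest on no test. Total sample 2 minus total sample 1 had an SD of 0.258 (log2) over 19950 genes and unnamed probes, which describes the spread between the 2 hybridisations of total RNA, and the number of arrays limits the precision.

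A set of 13 genes fixed in advance was examined first. KCNQ1OT1 is a lncRNA that stays at its own chromosomal locus. Its Cy5 level was 2.48-fold higher in the nuclear than in the cytoplasmic fraction, with the 2 arrays set directly against each other. With the totals as reference its log2 ratio was 1.45. Its cytoplasmic signal was not well above background, so the size of the difference is uncertain. RPLP0, which encodes a ribosomal stalk protein, was lower in the nuclear fraction by a log2 ratio of -1.35 (SD 0.20 over 2 probes). The glycolytic enzyme GAPDH had a nuclear over cytoplasmic log2 ratio of -0.93 and the elongation factor EEF1A1 of -0.84. MYC itself had a ratio of 0.76, below the 2-fold limit. ACTB (beta-actin) had -0.39 (SD 0.63 over 2 probes), and its brighter probe alone gave 0.06. MALAT1, NEAT1, MEG3, TUG1, GAS5, SNHG5 and ZFAS1 were also to be examined, but no probe was tied to them by an identifier that could be matched, and they are not analysed here.

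The comparison of the nuclear with the cytoplasmic fraction addressed which transcripts are kept in the nucleus and which are exported. Of 19950 genes and unnamed probes, 3019 (15.1%) were at least 2-fold higher in the nuclear fraction (nuclear-enriched) and 2148 (10.8%) were at least 2-fold higher in the cytoplasmic fraction (cytoplasm-enriched). Among 4404 protein-coding genes with a symbol, 376 (8.54%) were nuclear-enriched and 500 (11.4%) cytoplasm-enriched. By the same limit, total sample 2 differed from total sample 1 in 4 cases upward and 299 downward over all 19950, and in 1 and 9 of the protein-coding genes. The ratio is relative to the average transcript of each sample, since the arrays do not show how much RNA each fraction held. In the authors' value table the same limit gave 4738 nuclear-enriched and 5161 cytoplasm-enriched units, so the nuclear share of calls was 47.9% against 58.4% here. Of the 3019 nuclear-enriched units, 656 had a cytoplasmic signal that was not well above background, and 81 of the 2148 cytoplasm-enriched units had such a nuclear signal.

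The mRNAs with the highest nuclear ratios included HSPA6, an inducible heat shock chaperone of the HSP70 family, at a log2 ratio of 4.26 (19.2-fold). GCLM, the regulatory subunit of the enzyme that starts glutathione synthesis, was at 3.74 (13.4-fold). OGT, the enzyme that adds O-linked N-acetylglucosamine to proteins, was at 3.70, and FCRL5, a B-cell receptor of the Fc receptor-like family, at 3.58 (11.9-fold). The probes for FUT6 (a fucosyltransferase, 4.73), AS3MT (an arsenic methyltransferase, 4.37), MYO1C (an unconventional myosin, 4.24), the leptin receptor LEPR (4.21), ILDR1 (4.09) and BBS5 (3.70) completed the 10 highest. Total sample 1 read FUT6 at 17.01 and AS3MT at 16.89 (log2), above EEF1A1 at 16.17. MYO1C (14.78), LEPR (14.48) and FCRL5 (14.04) were also bright in total sample 1. Whether the probes of the 10 highest genes read those genes alone was not tested. For FUT6 and AS3MT the total signal itself differed between the arrays, by -1.94 and -1.97 for total sample 2 minus total sample 1. With the Cy5 levels of the 2 arrays set directly against each other, so that no total enters as reference, their ratios were 2.80 and 2.40. Of the mRNAs with the lowest ratios, FTL, the ferritin light chain, was at -2.86 (7.26-fold higher in the cytoplasm). CCDC85B was at -2.51, CDK2AP1 at -2.43, the RNA polymerase II subunit POLR2I at -2.29, the calcium-binding protein S100A11 at -2.28, the ribosome biogenesis factor NOP53 at -2.26 and the mitochondrial carrier UCP3 at -2.26. The ribosomal protein mRNAs RPL30 (-2.25), RPS3A (-2.22) and RPS19 (-2.20) completed the 10 lowest. Each of the highest and lowest mRNAs was read by 1 probe only.

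All 29 measured mRNAs for cytosolic ribosomal proteins were cytoplasm-enriched. Their median log2 ratio was -1.79 (SD 0.32 over genes), against -0.30 in random gene lists matched on total signal. It lay at percentile 0 of the 10000 random lists. All but 3 of the 29 genes had a mean total signal at or above a log2 of 14. Catalogue probes that bright, these genes included, had a median of -1.13, well below -0.30. The matching may therefore be loose at this brightness. The gap and the percentile can overstate how far these genes differ from equally bright probes. The ribosomal protein mRNAs ranged from RPL30 (-2.25) and RPS3A (-2.22) to RPS2 (-1.18) and RPL7A (-1.08). Their median was 0.41 above total in the cytoplasmic sample and -1.39 in the nuclear sample. Nuclear-encoded subunits of the respiratory chain and ATP synthase were likewise low in the nuclear fraction: 13 of 26 were cytoplasm-enriched, 13 passed neither limit, and the median of -1.04 (SD 0.82) lay at percentile 0.03. The small subunits COX6B1 (-2.11) and COX7C (-1.89) were at one end, and NDUFV1 (0.91) and ATP5F1B (0.44), which bind NADH and form the catalytic part of ATP synthase, at the other. Replication-dependent histone genes had a median of -0.98 (SD 0.39, percentile 0.01), with 7 of 15 cytoplasm-enriched, among them H2AC17 (-1.60) and H2BC12 (-1.25), while H3C2 (-0.70) and H3-4 (-0.35) were not.

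A list fixed in advance for transcripts known to keep introns, made up of genes for splicing and RNA-binding factors and of OGT, was at the opposite end. Of 18 measured, 12, OGT among them, were nuclear-enriched and none cytoplasm-enriched, and their median of 1.33 (SD 0.99) lay at percentile 100. OGT (3.70) and the RNA-binding protein RBM5 (2.63) were the highest, and SRSF5 (-0.04) and the export helicase DDX39B (0.04) the lowest. Other nuclear-enriched members were the RNA-binding protein RBM39 (2.46), the kinase CLK1 (2.03) and the serine/arginine-rich factor SRSF6 (1.41). Zinc-finger genes of the ZNF series had a median of 0.22 (SD 0.60, percentile 98.7), with 3 of 22 nuclear-enriched. ZNF195 (2.10) and ZNF84 (1.71) were the highest, ZNF14 (-0.15) and ZNF207 (-0.09) the lowest. Against random lists not matched on signal the ZNF list lay at percentile 97.3, not among the highest 2.5% of random lists.

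**Figure D1:**
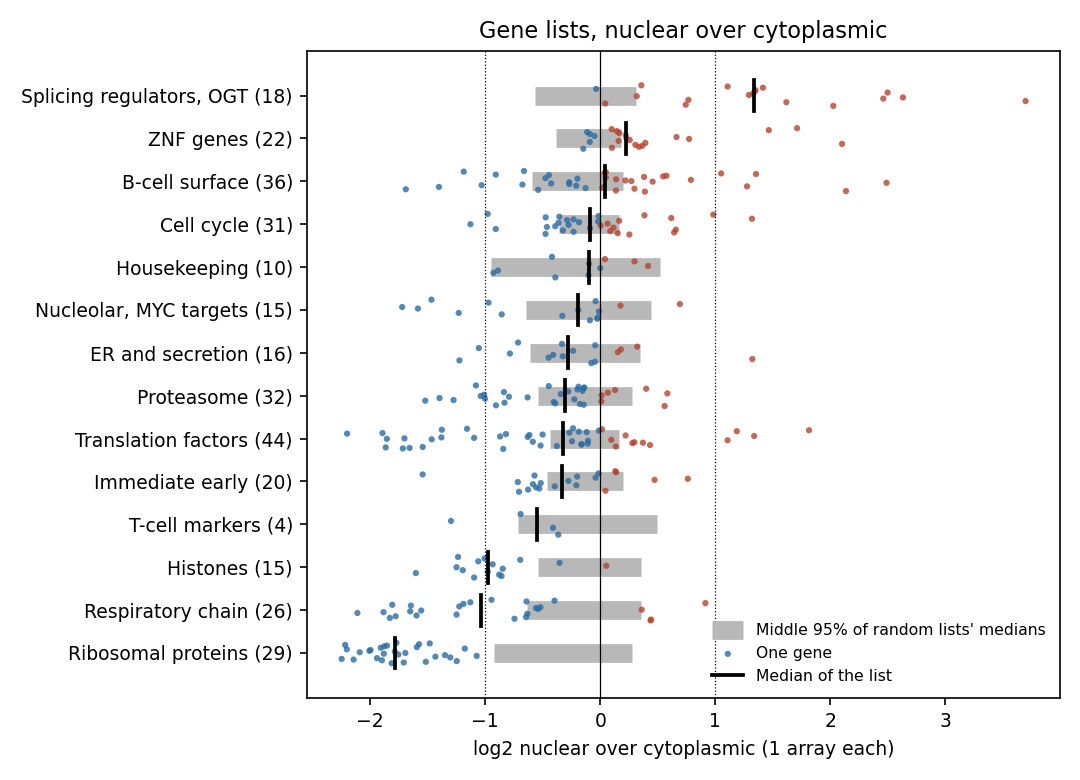
Nuclear over cytoplasmic log2 ratio (x axis) of each measured gene in the 14 lists with at least 3 measured genes (number in brackets). Each point is a gene, red above 0 and blue below it, black bars are list medians, grey bars span the medians of 10000 random lists matched on total signal without the lowest and highest 2.5%, and dotted lines mark 2-fold. The medians of the ribosomal protein (-1.79), respiratory chain (-1.04) and histone (-0.98) lists lie left of their grey bars, and those of the list of splicing regulators and OGT (1.33) and ZNF genes (0.22) right of theirs.

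Genes that define the B cell went both ways. Of 36 surface and antigen-presentation genes, 5 were nuclear-enriched and 4 cytoplasm-enriched, and the median of 0.04 (SD 0.88) lay at percentile 90.1. The costimulatory ligand CD86 (2.49) was the highest, the tetraspanin CD37 (-1.69) and the adhesion molecule CD48 (-1.40) the lowest. MS4A1, which encodes a membrane protein of B cells, was at 1.35. Both measured genes of the immunoglobulin list were low in the nuclear fraction, IGLL1 at -1.04 and the J chain gene JCHAIN at -0.99, the second short of the limit.

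The remaining lists had medians within the range of random lists, neither among the lowest nor among the highest 2.5%. Of 44 translation factors and related genes, 13 were cytoplasm-enriched and 4 nuclear-enriched (median -0.32, SD 0.93, percentile 12.8). The translation repressors EIF4EBP1 (-2.20) and EIF4EBP2 (-1.89, SD 0.50 over 2 probes) were the lowest and the initiation factors EIF5 (1.82) and EIF4A2 (1.34) the highest. Of 32 proteasome subunits, 7 were cytoplasm-enriched and none nuclear-enriched (median -0.31, SD 0.55, percentile 21.4), from PSMB2 (-1.52) and PSMB6 (-1.40) to PSMC6 (0.58) and PSMD2 (0.40, or -0.12 when arrays were centred on their medians without loess). Of 16 genes of the endoplasmic reticulum and secretion, the chaperone HSP90B1 (1.32) was nuclear-enriched, DAD1 (-1.23) and SEC61B (-1.06) were cytoplasm-enriched and RPN2 was at 0.18 (median -0.28, SD 0.60, percentile 27.4). Of 20 immediate-early genes, SOCS1 (-1.54) was cytoplasm-enriched (median -0.34, SD 0.50, percentile 12.7), followed by JUND (-0.72), and the highest were MYC (0.76) and KLF6 (0.47). Nucleolar and other MYC target genes had 4 of 15 cytoplasm-enriched (median -0.19, SD 0.74, percentile 37.2), including NME1 (-1.72) and NHP2 (-1.59), while NOP2 (0.69) and NOLC1 (0.18) were the highest. Of 31 cell-cycle genes, the helicase subunit MCM7 (1.32) was nuclear-enriched and CDK4 (-1.13) cytoplasm-enriched (median -0.09, SD 0.54, percentile 54.6). TOP2A was at 0.98 and TYMS at -0.98. None of 10 housekeeping genes passed the limit (median -0.10, SD 0.45, percentile 60.6), GAPDH (-0.93) and HPRT1 (-0.89) being the lowest and PGK1 (0.42, or -0.19 when arrays were centred without loess) and TBP (0.30) the highest.

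Markers of other blood cells were few. Of 11 T-cell markers on the array, 4 were measured, CD3G (-1.30), LCK (-0.69), CD3D (-0.41) and CD2 (-0.37), with a median of -0.55 (SD 0.43, percentile 8.15). Of 9 myeloid markers, the integrin ITGAM (1.71) and the scavenger receptor CD68 (-1.63) were measured. None of 6 erythroid and platelet markers had total signal well above background on both arrays.

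Named noncoding RNAs were also few, 5 lncRNAs with total signal well above background. PVT1, the lncRNA next to MYC, was nuclear-enriched at a log2 ratio of 2.11 (4.32-fold). LINC00467 (-1.65) and MIR155HG (-1.08), the host transcript of miR-155, were cytoplasm-enriched. NBR2, which the rule for named genes did not select and which was chosen after its value was seen, was at 0.16 with a cytoplasmic signal not well above background. No bound was computed for NBR2. Of the list of small nuclear and nucleolar RNAs, the RNase MRP RNA gene RMRP was nuclear-enriched at 2.31 and RN7SK, the 7SK RNA, was at -0.80. The RN7SK ratio, although short of the 2-fold limit, went against a nuclear location, and the reason was not tested. Signals for both lay above total in both fractions, RMRP by 0.41 in the cytoplasmic and 2.72 in the nuclear sample and RN7SK by 1.49 and 0.69. No probe could be tied to the list of small nucleolar RNA host genes or to mitochondrially encoded genes.

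Localisation of lncRNAs against mRNAs was the aim stated for the arrays. The files do not tie the 28523 custom-designed probes to transcripts, so this comparison set all custom probes against the probes of named mRNAs. Of 4787 custom probes with total signal well above background, 1301 (27.2%) were nuclear-enriched and 387 (8.08%) cytoplasm-enriched, against 8.66% and 11.2% of 4732 mRNA probes. Total sample 2 was at least 2-fold lower than total sample 1 in 245 custom probes and higher in 0, which raises a ratio that uses both totals. With the Cy5 levels of the 2 arrays set directly against each other, without a total, 1030 custom probes were nuclear-enriched and 427 cytoplasm-enriched. The median log2 ratio of the custom probes was 0.30, against -0.12 in random lists of mRNA probes matched on total signal (percentile 100), a difference of 0.42. That difference depended on the processing: it was 0.03 without a filter on dim probes, 0.90 in the authors' value table and 1.12 in the scanner software's log ratio. The custom probes come in 2 design sets. In the larger set the median was 0.48, and 1007 of 2963 probes were nuclear-enriched and 198 cytoplasm-enriched. In the smaller set the median was 0.02, and 294 of 1824 were nuclear-enriched and 189 cytoplasm-enriched. The median of the 5 named lncRNAs was 0.16 (percentile 81.9), the value of NBR2, which was dim in the cytoplasmic sample.

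**Figure D2:**
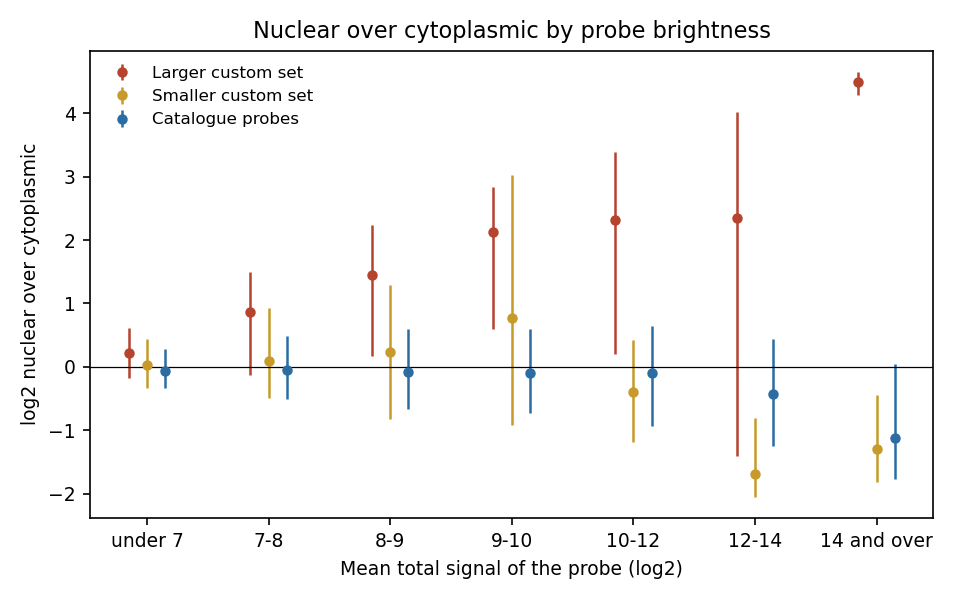
Nuclear over cytoplasmic log2 ratio (y axis) of probes grouped by their mean total signal (x axis, log2). Points are medians and lines span the middle 50% of probes, in red for the larger custom set, yellow for the smaller custom set and blue for catalogue probes, one hybridisation per fraction. The larger set's median goes from 0.22 under 7 to 4.49 at 14 and over, where the catalogue probes' median is -1.13.

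Each fraction was also set against the total RNA of its own array, where the dye and the fraction differ together and a probe's dye effect stays in the ratio. Relative to total RNA, 450 units were at least 2-fold higher and 1205 at least 2-fold lower in the cytoplasmic sample. In the nuclear sample, 1091 were higher and 908 lower, but 875 and 1026 against total sample 1 alone and 847 and 905 in the limma fit, so which side held more depended on the setting. HSPA6 was -3.37 in the cytoplasmic and 0.90 in the nuclear sample, PVT1 -0.78 and 1.33, RPS19 1.10 and -1.11, and FTL 0.13 and -2.73. With arrays centred on their medians without loess, 32 units were higher and 4428 lower in the cytoplasmic sample, and 224 higher and 3445 lower in the nuclear sample.

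If total RNA is a mix of both fractions, a transcript's total level lies between them. This held for 65.0% of the 19950 units, where unrelated signs of the ratios of the fractions to total would give 49.6%. Among units past 2-fold between nucleus and cytoplasm the share is high by construction and is not given. When arrays were centred on their medians without loess the share over all units was 31.5%, and unrelated signs would give 29.0%. Across the 58620 probes with values on both arrays, the ratios of the fractions to total correlated at -0.486 (Pearson's r across probes, which are not independent replicates). The direction of the ratios was taken from the labels, which state the dyes. The correlation would be the same with both ratios inverted, so it says nothing on direction.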

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

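Control spots entered no comparison. Among them, 10 spike-in probes with 35 spots each were set against the negative controls, and 3 stood out in Cy3, the total RNA channel. The criterion, a median above the upper 2.5% of negative control spots with at least 0.5 of the spots well above background, was settled after the values were seen. The brightest had a median signal of 268.5 for total sample 1 and 193 for total sample 2 (SD over spots 28.9 and 16.1), where the upper 2.5% of negative control spots began at 36.3 and 36. The next gave 83 and 63, and one gave 53 for total sample 1 alone by the same criterion. In Cy5 the brightest probe read 46 in the cytoplasmic and 39 in the nuclear sample, with 2 and 0 of 35 spots well above background. Another spike-in probe read higher in Cy5, at 51 in the cytoplasmic sample (10 of 35 spots well above background) and 45.5 in the nuclear sample, where the upper 2.5% of negative control spots began at 44 and 43, but too few of its spots were well above background to meet the criterion. No explanation, technical or biological, was tested.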

How the results depend on the processing

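Leaving out probes of very bright total signal and genes whose probes differ in sign was chosen after seeing the data, and all other alternatives were fixed before. Each fraction is 1 sample, so no alternative adds a replicate of it, and the dim end is limited by signal: the cytoplasmic median signal was 42 over a background of 34. Of 347 alternative values of the main results, 293 stayed within 1.5 times the count or within the spread used for the value, and 54 moved. For the moved values the cause was not tested, except that the thresholds act by construction. All 14 lists stayed on their side of the random lists in all 13 alternatives, but for the ZNF list, in 12. The 2 alternatives with a single total sample give the lists identical values by construction, and without probes at or above a log2 total of 14 the ribosomal protein list keeps 3 of its 29 genes, so that alternative hardly tests it. Of 1016 alternative values of named genes, 1013 kept their sign, but 130 of these moved by more than the spread used. Of 86 named genes, 42 moved so under median centring without loess, 31 in the authors' value table and 22 in the scanner software's log ratio. The 3 values that changed sign were ACTB with its brightest probe (0.057, from -0.391) and, under median centring without loess, PSMD2 (-0.12, from 0.399) and PGK1 (-0.194, from 0.416). With a single total sample as reference, that total cancels from the nuclear over cytoplasmic ratio. The ratio then compares the Cy5 levels of the 2 arrays directly, with no reference. Whichever total was kept, 2666 units were nuclear-enriched and 2266 cytoplasm-enriched, and no count changed by over 1.5 times. Nuclear over total was 875 higher and 1026 lower against total sample 1, so the larger side turned, as it did in the limma fit (847 and 905). Cytoplasmic over total was 627 higher and 978 lower against total sample 2. Without probes at or above a log2 total of 14 the counts were 2874 and 1968, without genes of differing probes 3017 and 2148, and in the limma fit, the only alternative with a test, 2555 and 2207.

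With a 1.5-fold threshold 4923 units were nuclear-enriched and 4335 cytoplasm-enriched, of mRNA genes 752 and 1077, and 739 custom probes were cytoplasm-enriched. Cytoplasmic over total gave 1538 higher and 2893 lower, nuclear over total 2839 and 2724. With a 4-fold threshold the nuclear-enriched and cytoplasm-enriched counts were 1016 and 205, of mRNA genes 64 and 29, of custom probes 557 and 63. Cytoplasmic over total gave 6 and 274, nuclear over total 194 and 28.

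The scanner software's log ratio, which has no offset, gave 5280 nuclear-enriched and 4948 cytoplasm-enriched units, of mRNA genes 577 and 1091, of custom probes 2258 and 1005. Cytoplasmic over total was 1674 higher and 3890 lower, nuclear over total 2354 and 2809. List medians minus those of random lists were 1.787 for splicing regulators and OGT (1.468 in the report's setting), 0.761 for ZNF genes (0.332) and -0.933 for T-cell markers (-0.401), and custom minus mRNA probes was 1.124 (0.416). The authors' value table gave 4738 and 5161 units, 1147 cytoplasm-enriched mRNA genes and 1055 such custom probes. Cytoplasmic over total was 1749 higher and 3221 lower, nuclear over total 2332 and 2983. Its list differences were 1.737 for splicing regulators and OGT, 0.699 for ZNF genes, -0.907 for T-cell markers and -1.118 for ribosomal proteins (-1.49), and custom minus mRNA probes was 0.895.

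Median centring without loess shifted the median nuclear over cytoplasmic ratio from -0.008 to 0.151, and the value table to -0.165. Under median centring, cytoplasmic over total was 32 higher and 4428 lower, nuclear over total 224 and 3445, total lay between the fractions for 31.47% (29.02% if signs were unrelated), and the list differences were -1.75 for ribosomal proteins and -0.471 for nucleolar genes (-0.084). Without a filter on dim probes custom minus mRNA probes was 0.026. Choosing the brightest probe was not run for custom against mRNA probes, which are compared probe by probe. No paired analysis was possible because each fraction has 1 sample, so the groups share fewer than 2 replicate numbers.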

Other observations

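The genes in this paragraph were chosen after their values were seen. OGA, the enzyme that removes the sugar that OGT adds, was nuclear-enriched like OGT, at a log2 ratio of 2.52 against 3.70. FTH1, the ferritin heavy chain, was at -2.13 beside the light chain FTL at -2.86. The metallothionein genes MT1E (-2.05), MT1X (-1.97) and MT1A (-1.94) and the spliceosomal Sm protein genes SNRPD2 (-2.08) and SNRPF (-2.08) were also cytoplasm-enriched, whereas the RNA-binding protein TIA1 was at 3.16 and the scaffold protein AKAP9 at 3.09. The histone genes H3C15 and H4C15 were the only 2 named genes at least 2-fold above total in both fractions, H3C15 by 3.81 in the cytoplasmic and 2.75 in the nuclear sample and H4C15 by 2.03 and 1.02. Over all 19950 units, 22 were, and 2 were at least 2-fold below total in both.

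Of the 5 tests below, those of the competition between samples and of the offset were set before their results were seen, the other 3 after, as was the slope within the larger custom set.

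The brightest probes of the larger custom set had nearly one ratio. Of its 111 probes with a mean total signal at or above a log2 of 14, 97 were past a log2 ratio of 3, with a median of 4.49 and the middle 50% between 4.30 and 4.65. A ceiling of the scanner is argued against by the saturation flags, which marked no spot in any of the 4 samples. The other 311 bright probes had a median of -1.18, a difference of 5.67 (bootstrap interval 5.47 to 5.87, from 1000 draws). Most of them were not high in the nuclear sample, so they cannot decide on a ceiling for bright nuclear spots. Of these, 36 were past 3 too, including those of FUT6, AS3MT, MYO1C, LEPR and FCRL5. A candidate explanation is one abundant nuclear sequence family, such as a repeat, read by many probes, which cannot be told apart from separate nuclear transcripts of similar location without the probe sequences, not used here. That 86.5% of the set's bright probes lay within 0.5 of their own median, 2.72 times the 31.8% among the other bright probes, is the pattern itself and supports neither.

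Total sample 2 read lower than total sample 1 on bright probes that were high in the nuclear sample, by a median of -1.30 (log2) over the 133 bright probes past a ratio of 3 against 0.09 over the other 289. Part of this contrast is by construction, because the ratio that picks the 133 probes contains total sample 1 minus total sample 2. The slope of total sample 2 minus total sample 1 on the raw nuclear minus cytoplasmic signal was then taken. A larger nuclear share in total sample 1 would push this slope downward at all brightness. Between log2 signals of 10 and 13 the slope was 0.049 (interval 0.039 to 0.060), and 0.058 (0.031 to 0.090) within the larger custom set. Each total sample shares its spots with a fraction, which pushes this slope upward, and its value without any difference is not known. The test therefore cannot decide on the nuclear share. At or above 14 without the probes past 3 the slope was -0.097 (interval -0.125 to -0.065). Competition between the 2 labelled samples of an array for the brightest spots would predict this. Quenching between the dyes, or a larger nuclear share in total sample 1, would predict the same. With competition, the nuclear ratios of these probes may be overstated (FUT6 was at 2.80 instead of 4.73 with the Cy5 levels set directly against each other, without a total as reference). The shift was not confined to bright spots: between 10 and 13 its median was -0.14 in the larger custom set and -0.01 in catalogue probes, and 169 of the 212 dimmer probes with total sample 2 at least 2-fold lower belonged to that set, and the cause there stays open.

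Probes of the larger custom set had higher nuclear ratios the brighter they were. The median was 0.22 over 1480 probes under a log2 of 7 and 2.32 over 155 probes between 10 and 12. The offset, which shrinks dim ratios, is argued against as the whole cause: in the scanner software's log ratio, which has no offset, the difference between these groups was 1.58 (interval 1.14 to 2.05), against 2.10 with it. This comparison speaks only to the offset. A limit on dim ratios from Cy5 signal near background stays open, since the comparison does not address it. A difference in the kind of transcript that dim and bright probes measure stays open too, and no biological explanation was tested.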
